A study of Mus musculus with 9 samples.

How the data were processed

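RNA was taken from isolated and cultured germ cells of C57Bl mice at the pachytene and diplotene stages, and libraries were made by poly-A capture with the KAPA Stranded mRNA-Seq kit, per the labels' protocols. There were 9 libraries in 3 groups of 3: untreated, 24 mM oxamate for 48 h, and 24 mM oxamate with 0.3 mM octyl-L-2HG. No culture time was given for the untreated cells. The submitters' processing notes name bcl2fastq 2.18.0.12, cutadapt 1.18, TopHat2 2.1.1, HTSeq 0.6.0, DESeq2 1.22.2 and GRCm38, with no parameters. How strand was used in counting is not given in the sources used here, so reads of overlapping or antisense genes may not be told apart.

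The deposited table holds 55471 genes with, per the file headers, a raw and a normalized column per library and the authors' log2 fold changes and adjusted p-values. The raw columns hold whole-number counts per gene deposited by the authors, with no normalization: all 442944 values were whole. The table writes a question mark where a gene has no value, for 6255 genes in all 9 raw columns, most of them small RNAs and immune receptor segments; these genes were left out. Because of those cells the raw columns were entered in the record of units as another unit, although their values are counts. The 9 normalized columns were not used. Library totals ran from 24849620 to 46671048 counts, so counting error is small beside the spread between libraries for all but low genes.

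The design fixed before the data were examined named edgeR's quasi-likelihood test as the main test, but edgeR was not used here, since the record of units does not hold the unit counts that its use required. Limma-voom on the counts, which had been planned as an alternative, took its place for every result. This is a departure from the planned design, made because of how missing genes are written and not because of the counts themselves. It was decided before any fit was run here, when the authors' own numbers of called genes had been seen. DESeq2 was not used here either, apart from the authors' own use of it.

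Genes were kept when at least 3 libraries reached the CPM that 10 counts give in the median library and the total was at least 15, which left 18234 genes. Libraries were scaled by the trimmed mean of M values (TMM), trimming 30% of log ratios and 5% of log levels, written out in R 4.3.3. Log2 CPM with an offset of 0.5 were fitted with limma 3.58.1 (voom, robust empirical Bayes), all 9 libraries in one fit with a mean per group. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. CPM values are TMM-scaled, with SD over 3 libraries.

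The 35 gene lists, with 794 symbols, were fixed before the data were examined; 31 symbols were matched through older names and 1 was not matched. Lists of X-linked and Y-linked genes were added by chromosome. Each list was tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated one, adjusted over the 37 lists of a comparison. With an estimated correlation no list passed in any comparison, and the smallest adjusted p was 0.23. Calls were lost also where the estimated correlation lay below the preset 0.01. In oxamate against untreated the Leydig cell list, estimated at -0.12, went from a camera adjusted p of 0.037 to 0.51. The list of p53 targets, estimated at 0, went from 0.0061 to 0.43. A lost call therefore does not by itself show that the genes of a list vary together.

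Genes are named by a rule set before the data were examined. It takes the 10 largest rises and 10 largest falls (5 of each in the third comparison) among genes past the threshold whose 3 libraries in one group all lie above those of the other and whose mean CPM is at least 2 in the higher group. Unnamed gene models are left out. It adds the 3 members with the smallest p of each list and a fixed set, of which those reported are Ldha, Ldhb, Ldhc, D2hgdh, Sycp3, Piwil1, Ddx4, Acrv1 and Prm1.

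No label says what the letters A to C mark. Between untreated and oxamate libraries, the deviations of same-letter libraries from their group means correlated across genes at 0.40, 0.40 and 0.29, all over 0.1, so the letters were taken to pair these libraries, and the fit with the letter as a block is given beside that result. In the other comparisons the correlation for letter C was 0.04 and 0.06. This rule was applied in the same exploratory output that showed the counts of both fits. All pairs of libraries within a group differed by more than sampling noise.

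The procedure was tested on simulated counts for oxamate against untreated, with 18234 genes of which 200 were changed. At 1.5-, 2- and 4-fold it recovered 25.4%, 56.7% and 75.8% of the changed genes, with 3 false calls among 108. A limit of more than 80% recovered at 4-fold had been set for this test and was not met. Most of the missed genes had few counts: among genes with a mean of at least 50 counts, 95.5% were recovered at 4-fold. The limit was then replaced by limits on scaling, false calls and direction. A list of raised genes was called by camera, and 2 of 50 random unchanged lists had an unadjusted p under 0.05. Simulated genes were drawn independently, so this does not test the preset correlation of 0.01 for lists whose genes vary together. Camera with an estimated correlation was not run on the simulated counts, so its power to call a raised list is not known. In oxamate against untreated the estimated correlation ran from -0.14 for Sertoli markers to 0.81 for mitochondrially encoded genes. It was 0.25 for X-linked genes.

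Alternatives covered scaling, the filter on low counts, the samples in the fit, the replicate block, thresholds, the list correlation and leaving out each library. Limma-trend, removal of trends with exon length and GC content (from GENCODE M21 annotation, available for 99.8% of tested genes) and tests of Gene Ontology terms were added after the data were seen.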

Results

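Gene expression was measured by poly-A RNA sequencing in cultured mouse spermatocytes at the pachytene and diplotene stages of meiotic prophase, stages at which homologous chromosomes are paired in synapsis (pachytene) and then come apart while held by crossovers (diplotene). The X and Y chromosomes are transcriptionally silenced in pachytene cells. The 9 libraries fell into 3 groups of 3, with the letters A, B and C in each group. One group was untreated. The second received 24 mM oxamate, a pyruvate analog that inhibits lactate dehydrogenase, for 48 h. The third received the same oxamate dose and, in addition, octyl-L-2-hydroxyglutarate (octyl-L-2HG) at 0.3 mM, an esterified, cell-permeable form of L-2-hydroxyglutarate, a metabolite that lactate dehydrogenases can produce and that inhibits 2-oxoglutarate-dependent dioxygenases. Library totals ranged from 24849620 to 46671048 counts. Of 49216 genes with a count, 18234 were tested. The labels do not say whether libraries of a group came from separate cultures or animals, so the p-values measure the spread between these libraries, which may be technical. Coordinates are on GRCm38, as deposited.

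The comparison of oxamate with untreated cells asks which transcripts differ after 48 h with this inhibitor of lactate dehydrogenase. No culture time was given for the untreated cells, which may not have been cultured for 48 h. In every comparison with untreated cells, effects of treatment therefore cannot be told apart from those of time in culture. Genes were ranked only if their mean was at least 2 CPM in the higher group. Among these the largest named rises were those of Trp63, a p53-family transcription factor, Ccng2, a cyclin G, and Nova1, an RNA-binding splicing regulator, at 3.55-, 3.30- and 3.19-fold. The largest named falls were those of Ptpn3, a tyrosine phosphatase, and Tpd52, at 4.39- and 4.34-fold. Ptpn3 (ENSMUSG00000038764, chromosome 4, 57190841 to 57301837) went from 36.8 ± 0.843 CPM in untreated cells to 8.55 ± 1.70 CPM with oxamate (mean ± SD, n = 3 libraries each), a log2 change of -2.13 (SE 0.13, limma adjusted p = 5.1e-05). Rab11fip3, an effector of Rab11 in endosome recycling (chromosome 17, 25989036 to 26069555), went from 8.62 ± 0.612 to 27.2 ± 2.66 CPM (log2 change 1.65, SE 0.12, limma adjusted p = 0.00023). Rufy1, Zfp455, Stc2, Palm, Epm2aip1 and Cflar were the other rises named by this ranking, between 2.57- and 2.88-fold. Rdm1, Mfsd4b1, Cyp2d22, Ldhd, Elobl, Fam214b, Vmn2r1 and Itgal were the other falls named by it, between 2.95- and 3.86-fold.

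In all, 1747 genes changed with oxamate, 1047 higher and 700 lower, by limma-voom at an adjusted p under 0.05. The split between rises and falls depended on the fit. It was 889 and 833 with upper quartile scaling, 902 and 982 with trends with length and GC content removed, and 1907 and 2254 when the letter was also a block. The median absolute log2 change of the 1747 genes was 0.61, and 287 changed at least 2-fold. The 3 libraries of one group did not overlap those of the other for 33.9% of tested genes, where chance gives 10%. Same-letter libraries deviated together in these groups, and a fit with the letter as a block called 4032 genes, 2210 higher and 1822 lower, among them all 1747. The count depended on single libraries: it was 572, 545 and 344 without untreated library A, B or C, and 693 and 608 without oxamate library B or C.

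Ldha encodes a somatic subunit of lactate dehydrogenase, the enzyme that oxamate inhibits. Its transcript fell 1.21-fold, from 1250 ± 3.17 to 1039 ± 69.4 CPM (n = 3 each, limma adjusted p = 0.045). The testis-specific Ldhc was also lower, at 3640 ± 76.4 and 3013 ± 244 CPM, and narrowly missed the threshold (limma adjusted p = 0.053). These values do not show a different response of Ldha and Ldhc. Ldhb was too low to test, with 1 to 8 counts in each library. D2hgdh, which oxidizes D-2-hydroxyglutarate, stood at 2.86 ± 0.465 and 2.94 ± 0.143 CPM. Of the 17 tested genes of lactate dehydrogenase and 2-hydroxyglutarate metabolism, 1 rose and 3 fell, and 2 rose and 4 fell when adjusted over the list alone. The list's median log2 change was 0.03 and its mean -0.12 (list test adjusted p = 0.39). Ldhd, which encodes a D-lactate dehydrogenase, fell 3.31-fold.

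Of 26 tested pachytene regulators and pachytene-expressed genes 3 fell and none rose with oxamate, Adam2, Tbpl1 and Adam3, with log2 changes of -0.28, -0.31 and -0.31. Adjusted over the list alone 4 rose and 7 fell, as with the letter as a block (list test adjusted p = 0.39). The germline RNA helicase Ddx4 (1024 ± 65.5 and 1064 ± 116 CPM), the PIWI protein gene Piwil1 (650.1 ± 23.9 and 587 ± 45.6 CPM) and the synaptonemal complex gene Sycp3 (168 ± 12.6 and 178 ± 29.8 CPM) did not pass the test. None of the 25 tested piRNA pathway genes passed by limma-voom, over all genes or adjusted over the list alone. With the letter as a block 4 rose and 2 fell. Of the 29 tested meiotic recombination genes, 2 rose and none fell, and 1 rose when adjusted over the list alone; with the letter as a block 2 rose and 1 fell. The 2 that rose over all genes were Ccdc36, which acts in double-strand break formation, at a log2 change of 0.65, and Ankrd31, a partner in the same process, at 0.40.

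**Figure D1:**
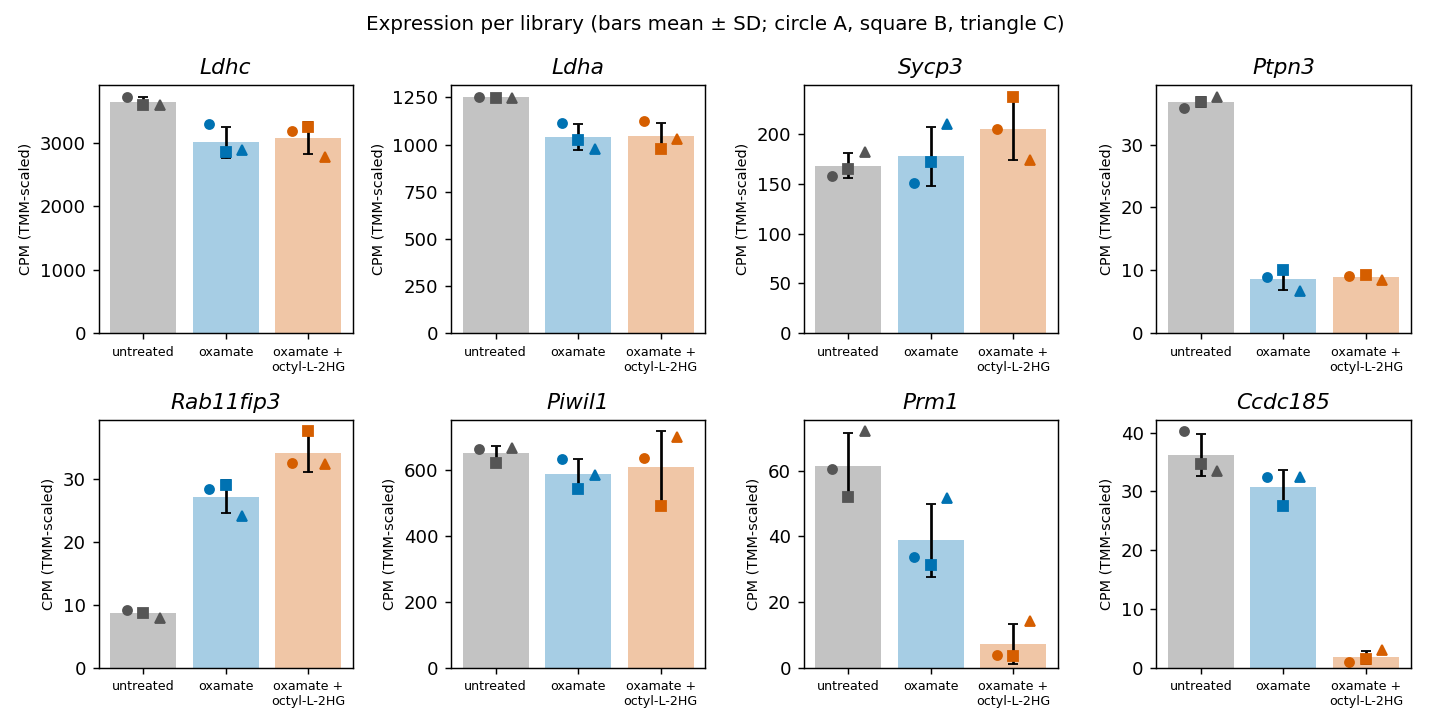
TMM-scaled CPM (vertical axes, linear from 0) of 8 genes in the 3 groups; bars are means, error bars SD (n = 3), and points the libraries A, B and C. Ptpn3 and Rab11fip3 differed between untreated and oxamate libraries and Prm1 and Ccdc185 between oxamate and octyl-L-2HG libraries, while Piwil1 overlapped across the groups.

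Genes on the X chromosome were higher with oxamate. Of 409 tested X-linked genes, 51 rose and none fell (60 rose and 2 fell when adjusted over the list alone, and 85 and 2 with the letter as a block), and their median log2 change was 0.25, against -0.01 for autosomal genes. With no filter on low counts the median was 0.11 over 1367 X-linked genes (adjusted p = 0.023). The camera list test called the X-linked genes higher (adjusted p = 1.8e-05 with a preset correlation of 0.01), but not with an estimated correlation (adjusted p = 0.71). Atp6ap2, an accessory subunit of the vacuolar proton pump (chromosome X, 12587801 to 12617049), rose 4.32-fold, from 0.398 ± 0.0724 to 1.74 ± 0.0629 CPM. Fmr1, the fragile X RNA-binding protein gene, rose 2.15-fold and Ofd1, a centriole and cilium gene, 2.42-fold. Of 49 tested Y-linked genes 1 rose and none fell, with none past the threshold when adjusted over the list alone. Their median was 0.23 (camera adjusted p = 0.033, and adjusted p = 0.71 with an estimated correlation). The camera call was lost without oxamate library C (median 0.14, adjusted p = 0.083). It was also lost with no filter on low counts (median 0.09, adjusted p = 0.23) and with at least 1 CPM in 3 libraries (median 0.18, adjusted p = 0.13). Over the alternatives the median ran from 0.09 to 0.25.

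With oxamate 4 lists of stress and immediate early responses were called higher. Of 21 tested p53 targets and apoptosis genes, 6 rose and none fell (8 rose when adjusted over the list alone), including the p53-family gene Trp63, the BH3-only gene Pmaip1 at a log2 change of 1.08 and the sestrin Sesn1 at 0.77. The list test gave adjusted p = 0.0061, and adjusted p = 0.43 with an estimated correlation. Of 32 tested amino acid response genes, targets of the transcription factor ATF4, 4 rose and none fell (7 rose when adjusted over the list alone), led by Aldh1l2, a mitochondrial folate enzyme, at 2.05, the amino acid transporter Slc38a2 at 1.20 and the stanniocalcin Stc2 at 1.49. That list's test gave adjusted p = 0.016, and adjusted p = 0.71 with an estimated correlation; without oxamate library A it gave 0.15. Of 22 tested unfolded protein response genes, 6 rose and 1 fell, the same counts as when adjusted over the list alone, with the chaperone Hyou1 at 0.50, the sensor Ern1 at 0.75 and the chaperone Canx at 0.35 (list test adjusted p = 0.036, and adjusted p = 0.51 with an estimated correlation). Of 12 tested immediate early genes 2 rose, also when adjusted over the list alone: Egr1, by 0.81, and Jun, by 0.67 (list test adjusted p = 0.016, and adjusted p = 0.51 with an estimated correlation). With the letter as a block 8 p53 targets, 12 amino acid response, 7 unfolded protein response and 3 immediate early genes rose, and 1 amino acid response and 1 unfolded protein response gene fell. The lists of heat shock proteins and of NRF2 targets, of the response to oxidative stress, had negative medians, -0.11 over 16 and -0.19 over 18 tested genes, and did not pass (list test adjusted p = 0.49 and 0.39). Of the heat shock genes 1 rose and 1 fell (1 and 3 when adjusted over the list alone), and of the NRF2 targets 1 rose (4 rose and 2 fell when adjusted over the list alone).

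Among the 2-oxoglutarate-dependent histone demethylases, the enzyme class that 2-hydroxyglutarate inhibits, 8 of 23 tested genes rose and 4 fell with oxamate (10 rose and 4 fell when adjusted over the list alone). In the blocked fit 11 rose and 4 fell. Kdm2b rose by 0.61, Kdm7a by 0.74 and Jmjd1c by 0.45 on the log2 scale. The list test gave adjusted p = 0.016, and adjusted p = 0.52 with an estimated correlation. No gene among 22 tested DNA and histone methylation enzymes changed by limma-voom, over all genes or adjusted over the list alone, and 5 rose with the letter as a block. Of 15 tested TET, prolyl hydroxylase and AlkB dioxygenases, 1 rose and 1 fell: the RNA demethylase Alkbh5, by 0.62, and Alkbh4, with a log2 change of -0.48.

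Genes of translation and energy metabolism had lower medians with oxamate, while few single members passed in the fit without a block. Cytosolic ribosomal protein genes had a median log2 change of -0.26, with 43 of 48 negative; only Rpl10l passed over all genes, at -0.38, and none when adjusted over the list alone (list test adjusted p = 4.4e-06, and adjusted p = 0.70 with an estimated correlation). With the letter as a block 26 of them fell, as did 13 respiratory chain, 7 TCA cycle and 5 glycolysis genes, while 1 glycolysis gene and 3 mitochondrially encoded genes rose. Of 38 tested nuclear-encoded respiratory chain genes 2 fell, the complex III subunits Uqcrfs1 and Uqcrq, and none when adjusted over the list alone. Their median was -0.18 (list test adjusted p = 0.002, and adjusted p = 0.71 with an estimated correlation). The TCA cycle list was also called, where 1 of 23 tested genes fell, Pdha2, also when adjusted over the list alone (list test adjusted p = 0.036, and adjusted p = 0.70 with an estimated correlation). In glycolysis 2 of 20 tested genes fell, also when adjusted over the list alone: Pgam2, with a log2 change of -0.32, and Eno1, with -0.43 (list test adjusted p = 0.0066, and adjusted p = 0.70 with an estimated correlation). The 11 tested mitochondrially encoded genes all had positive log2 changes with a median of 0.50, and none passed alone, over all genes or over the list alone (list test adjusted p = 0.016, and adjusted p = 0.71 with an estimated correlation; adjusted p = 0.18 without oxamate library C).

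**Figure D2:**
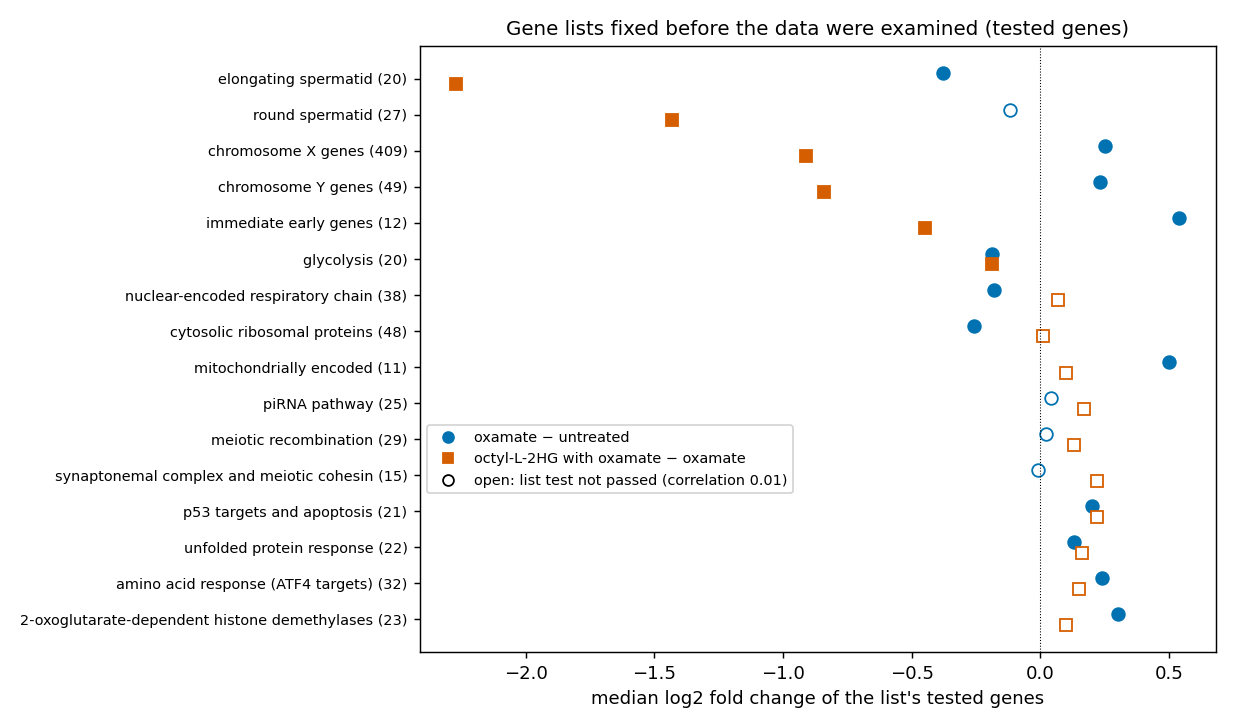
Median log2 fold change (horizontal axis) of 16 gene lists, with the number of tested genes in parentheses; circles are oxamate minus untreated, squares octyl-L-2HG with oxamate minus oxamate, and open symbols did not pass the camera test at a preset correlation of 0.01. Elongating and round spermatid genes lay at -2.27 and -1.43 with octyl-L-2HG, and no list passed with an estimated correlation.

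The comparison of octyl-L-2HG plus oxamate with oxamate alone asks what octyl-L-2HG adds to oxamate-treated cells. No group received octyl-L-2HG without oxamate, or another octyl ester. Effects of the metabolite therefore cannot be told apart from those of the esterified form. Genes of spermatids, the haploid cells that follow meiosis, were much lower with octyl-L-2HG. The largest named falls were those of Fam71b (26.7-fold), Spata31d1c (25.2-fold), Spata31d1b (24.3-fold), Abhd16b (23.0-fold) and Fam71a (22.6-fold), followed by Actrt3, Fndc8, Trim42, Ccdc185 and Spem1 at 18.8- to 21.9-fold. Fam71b (ENSMUSG00000020401, chromosome 11, 46396559 to 46407982) went from 29.1 ± 4.37 CPM with oxamate to 1.31 ± 0.977 CPM with octyl-L-2HG (n = 3 each), a log2 change of -4.74 (SE 0.35, limma adjusted p = 2.9e-05). Ccdc185 (chromosome 1, 182747126 to 182749180) went from 30.8 ± 2.88 to 1.79 ± 1.09 CPM. The Spata31d1 and Fam71 genes belong to multigene families whose reads the counting could split, so their single values are uncertain.

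In total 3550 genes changed, 749 higher and 2801 lower, and 2282 of the lower genes but 38 of the higher ones changed at least 2-fold. The groups did not overlap for 33.2% of tested genes, where chance gives 10%. The rises depended on the fit: 146 genes were higher when only these 6 libraries were fitted and 252 without octyl-L-2HG library A, where the count of changed genes was 2298. With the letter as a block 1991 were higher and 3214 lower. Octyl-L-2HG library C lay between the other libraries of its group and the oxamate libraries on the first principal component, at 49.6 against 100 and 103.

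Of 27 tested round spermatid markers 20 fell and none rose, with a median log2 change of -1.43, and of 20 tested elongating spermatid markers 17 fell and none rose, with a median of -2.27; the counts were the same when adjusted over the list alone. Actl7a, an actin-related protein of the acrosome, fell 4.01-fold, the testis-specific kinase Tssk2 4.49-fold and the acrosomal membrane protein Spaca1 2.93-fold. Among elongating spermatid genes the heat shock protein Hspa1l fell 8.61-fold, Spata18 2.39-fold and Spem1 18.8-fold. Prm1, the protamine that packs sperm DNA, went from 38.8 ± 11.1 to 7.17 ± 6.01 CPM (6.39-fold, limma adjusted p = 5e-04), and Acrv1, an acrosomal protein gene, from 47.6 ± 1.56 to 20.9 ± 7.85 CPM (2.38-fold, limma adjusted p = 7e-04). The list tests gave adjusted p = 1.9e-10 for round and 6.1e-14 for elongating spermatid genes, and adjusted p = 0.40 for each with an estimated correlation. In oxamate against untreated 1 round spermatid marker fell, Actl9, also when adjusted over the list alone, and no elongating spermatid marker passed either way. In the fit with the letter as a block 4 round and 2 elongating spermatid markers fell. The elongating spermatid list had a median of -0.38 (list test adjusted p = 0.016, and adjusted p = 0.71 with an estimated correlation).

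Sex-linked genes fell with octyl-L-2HG. Of 409 tested X-linked genes 210 fell and 1 rose (241 and 1 when adjusted over the list alone), 51.3% against 14.5% of autosomal genes, with a median log2 change of -0.91. With no filter on low counts the median was -0.41 over 1367 genes (adjusted p = 9.4e-06). Zfp185 (chromosome X, 72987339 to 73031543) fell 9.06-fold, from 1.83 ± 0.201 to 0.194 ± 0.0366 CPM. Of 49 tested Y-linked genes 17 fell and none rose (22 fell when adjusted over the list alone), with a median of -0.84. The list tests gave adjusted p = 1.5e-25 for X and 3.8e-05 for Y, and adjusted p = 0.40 and 0.61 with an estimated correlation. The spermatid markers fell in these same libraries.

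**Figure D3:**
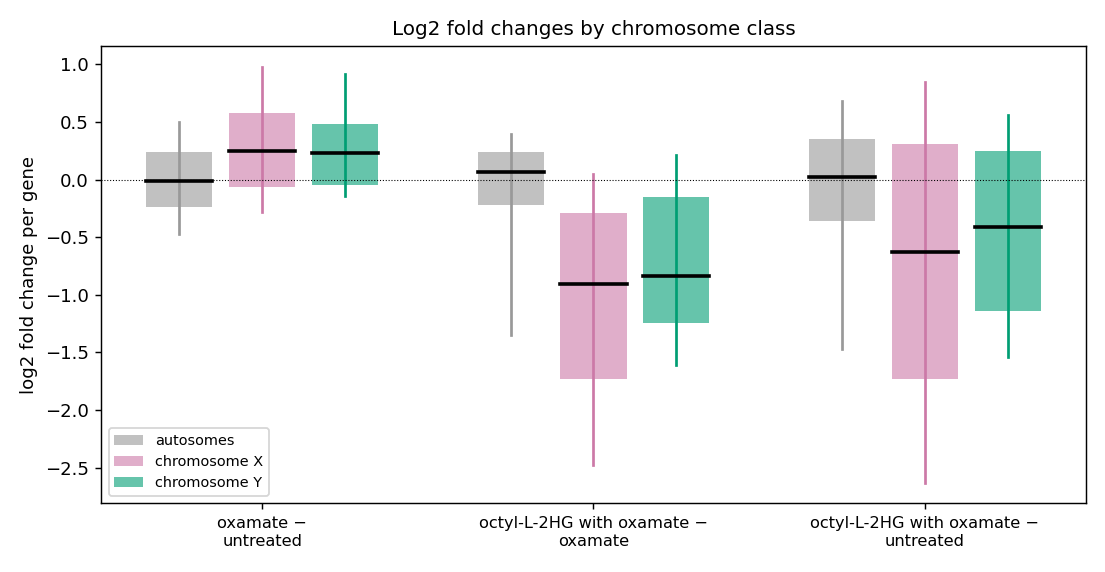
Log2 fold change per gene (vertical axis) for autosomal, X-linked and Y-linked genes in the 3 comparisons; black lines are medians, boxes the middle 50% and thin lines the 10th to 90th percentiles. The X-linked median was 0.25 for oxamate minus untreated and -0.91 for octyl-L-2HG with oxamate minus oxamate.

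Lists of meiotic prophase genes did not pass the list test in the fit without a block. None of 25 tested piRNA pathway genes passed with octyl-L-2HG by limma-voom, over all genes or adjusted over the list alone; their median log2 change was 0.17 (list test adjusted p = 0.063). With the letter as a block 8 rose and the list test passed (adjusted p = 0.022), but not with an estimated correlation (adjusted p = 0.65). Over the alternatives its adjusted p ran from 0.011, without octyl-L-2HG library B, to 0.65. Sycp3 stood at 206 ± 31.9 CPM, Piwil1 at 609 ± 108 CPM and Ddx4 at 1165 ± 146 CPM, none past the threshold. Of 21 tested genes of meiotic silencing and DNA damage signalling 5 rose and none fell, also when adjusted over the list alone, with the checkpoint clamp gene Hus1 at a log2 change of 0.43, the kinase Atr at 0.28 and Hormad1 at 0.34. Of 15 tested synaptonemal complex and meiotic cohesin genes 3 rose and 2 fell (4 and 2 when adjusted over the list alone), with Syce2 at -0.93, Hormad2 at 0.50 and the cohesin subunit Rec8 at -1.10.

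Glycolysis genes and immediate early genes also had falling members, in the same libraries in which the spermatid markers fell. In glycolysis 6 of 20 tested genes fell and none rose, also when adjusted over the list alone: Pkm, pyruvate kinase, had a log2 change of -1.95, Gpi1 of -0.94 and the pyruvate dehydrogenase kinase Pdk3 of -2.02 (list test adjusted p = 0.016, and adjusted p = 0.65 with an estimated correlation; adjusted p = 0.052 without oxamate library B). Gapdhs, the spermatogenic glyceraldehyde-3-phosphate dehydrogenase, stands in both the glycolysis and the elongating spermatid list and had a log2 change of -2.30; it was picked out after its values were seen. Of 12 tested immediate early genes 5 fell (6 when adjusted over the list alone), with Egr3 at -2.23, Nr4a1 at -1.74 and Klf4 at -1.45 (list test adjusted p = 0.013, and adjusted p = 0.40 with an estimated correlation). Ldha (1044 ± 73.7 CPM) and Ldhc (3072 ± 253 CPM) differed from the oxamate libraries by less than the spread between libraries. Of the histone demethylases 2 rose and 1 fell, also when adjusted over the list alone: Jmjd1c rose by 0.38, Kdm3a by 0.28, and the X-linked Phf8 had a log2 change of -2.44. The largest named rises were small, from 2.1-fold for the olfactory receptor gene Olfr25 down to 1.65-fold for the septin Sept2, with Olfr161, Gcsam, Chrnb3, Alg10b, Fan1, Slc16a6, Lamp5 and Zfp455 between.

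Markers of other testis cells were mostly too low to test. Of the tested markers 4 were of Sertoli cells, 4 of Leydig cells, 11 of peritubular myoid cells and fibroblasts, 9 of endothelium and 6 of macrophages and other leukocytes. With oxamate against untreated 1 Leydig marker fell, Star, and 2 when adjusted over the list alone (list test adjusted p = 0.037, and adjusted p = 0.51 with an estimated correlation). In the other cell types 2 peritubular markers rose, and 1 endothelial and 1 leukocyte marker fell. With octyl-L-2HG against oxamate no Sertoli or Leydig marker passed over all genes (1 Leydig marker fell when adjusted over the list alone), 3 peritubular markers fell and 1 rose, 3 endothelial markers fell and 1 leukocyte marker fell. Of 15 tested spermatogonial and early meiotic markers 1 fell, the X-linked Esx1.

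Whether octyl-L-2HG moved the genes changed by oxamate back was asked directly. Of the genes changed by oxamate, 101 changed in the opposite direction with octyl-L-2HG and 219 in the same direction. Of the 1047 raised genes 61 fell, where independent lists give 161, and 160 rose further, where independent lists give 43.0. Of the 700 lowered genes 40 rose, where independent lists give 28.8, and 59 fell further, where they give 108. Both comparisons use the oxamate libraries with opposite sign, which favors opposite changes over changes in the same direction. Part of the excess of lowered genes that rose may therefore come from these shared libraries. In 100 simulations of unchanged groups the correlation of log2 changes across genes averaged -0.48 and the covariance -0.0323. The count of opposite calls averaged 0.01, but unchanged groups give almost no calls by construction. That count therefore does not tell how many of the 101 opposite changes come from the shared libraries. The observed correlation was 0.14 and the covariance 0.0519, so the difference of covariances was 0.0842. Genes are not independent replicates. The simulated noise was independent between libraries, while same-letter untreated and oxamate libraries deviated together. Such shared deviations could make the covariance of unchanged groups less negative, so the difference may be overstated. The count of opposite changes was 22, 18 and 9 without untreated library A, B or C, 25 without oxamate library B or C, and 49 and 171 without octyl-L-2HG library A or C. The count of changes in the same direction was 59, 44 and 25 without untreated library A, B or C, 130, 56 and 77 without oxamate library A, B or C, and 115 without octyl-L-2HG library A. With the letter as a block 441 genes changed in opposite directions and 719 in the same direction.

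The same question was asked with oxamate libraries that took no part in the choice of genes. Genes raised by oxamate, chosen without 1 oxamate library, lay 0.59 ± 0.15 above untreated in the held-out library (median log2, mean ± SD over 3 held-out libraries), and octyl-L-2HG lay a further 0.22 ± 0.07 above it. Over all tested genes the median log2 change with octyl-L-2HG against oxamate was 0.07. The sets held 423 to 1208 raised, 190 to 854 lowered and 15 to 53 X-linked raised genes. The 3 values share the octyl-L-2HG libraries, so their SD leaves out the spread between those libraries. Distances from untreated reuse the untreated libraries that chose the genes, which favors larger distances. Deviations of same-letter oxamate and octyl-L-2HG libraries correlated at 0.31 for A, 0.39 for B and 0.04 for C. The choice of genes is therefore not fully independent of the octyl-L-2HG mean, which favors further change in the same direction. Genes lowered by oxamate lay at -0.53 ± 0.21 in the held-out library, and octyl-L-2HG differed from it by 0.01 ± 0.13. X-linked genes raised by oxamate lay at 1.08 ± 0.26 in the held-out library, and octyl-L-2HG lay at -0.21 ± 0.11 from it. All 409 tested X-linked genes had a median of -0.91 in that comparison, and the 51 that rose with oxamate a median of -0.30. Of the 51 X-linked genes that rose with oxamate, 4 fell with octyl-L-2HG, namely Usp9x, Rbm10, Alg13 and Brwd3, which were picked out after their values were seen. Their number is small, and 28 of the 51 were still higher with octyl-L-2HG than in untreated cells. The 51 had been chosen as higher than these same untreated libraries, which favors such a count.

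The comparison of octyl-L-2HG plus oxamate with untreated cells gives the combined difference. It counted 6988 changed genes, 3143 higher and 3845 lower, of which 557 and 2484 changed at least 2-fold. The count of higher genes was 2094 and 1990 without untreated library B or C. Among genes with a mean of at least 2 CPM in the higher group, the largest named rises were those of Zfp455 (4.82-fold), Trp63 (4.66-fold), Rab11fip3 (3.91-fold), Nova1 (3.68-fold) and Gata3 (3.57-fold). The largest named falls among them were those of Abhd16b (41.7-fold), Actrt3 (39.5-fold), Spata31d1c (38.2-fold), Trim42 (36.8-fold) and Fam71a (34.7-fold). Ldhc was 1.19-fold lower than in untreated cells (limma adjusted p = 0.029). Of 20 tested glycolysis genes 13 fell and 2 rose (14 and 2 when adjusted over the list alone; list test adjusted p = 0.00072, and adjusted p = 0.64 with an estimated correlation). Of 32 tested amino acid response genes 13 rose and 1 fell, also when adjusted over the list alone (list test adjusted p = 0.0036, and adjusted p = 0.70 with an estimated correlation), and Asns, asparagine synthetase, was the one that fell, with a log2 change of -2.20. Of 27 round spermatid markers 21 fell and of 20 elongating spermatid markers 17 fell, while 22 and 18 fell and 0 and 1 rose when adjusted over the list alone (list tests adjusted p = 8.5e-09 and 2.5e-10, and adjusted p = 0.51 for each with an estimated correlation). X-linked genes had 40 rises and 191 falls, with a median of -0.63 (list test adjusted p = 8.7e-06, and adjusted p = 0.70 with an estimated correlation; with no filter on low counts the median was -0.04 and adjusted p = 0.11). The p53 targets had 8 rises and 1 fall (10 and 1 when adjusted over the list alone) and the unfolded protein response 6 rises and 0 falls over all genes and over the list alone (list tests adjusted p = 0.0026 and 0.004, and adjusted p = 0.23 for each with an estimated correlation). Mitochondrially encoded genes had 4 rises (5 when adjusted over the list alone), and meiotic silencing and DNA damage signalling genes 8 (9 when adjusted over the list alone). Their list tests gave adjusted p = 0.03 each, and adjusted p = 0.70 and 0.64 with an estimated correlation. Endothelial markers had 3 falls (4 when adjusted over the list alone) and ribosomal protein genes 11 falls and 1 rise (0 when adjusted over the list alone), with list tests at adjusted p = 0.038 and 0.012, and adjusted p = 0.64 and 0.70 with an estimated correlation.

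The authors' deposited table holds its own calls, over 26033 tested genes. For oxamate against untreated the authors' deposited table lists 1377 genes higher and 962 lower at an adjusted p under 0.05. Of the 1747 genes called here, 1556 are called with the same sign in the authors' deposited table and 0 with the opposite sign. For octyl-L-2HG with oxamate against oxamate the authors' deposited table lists 826 higher and 2576 lower. Of the 3550 genes called here in that comparison, 3036 are called with the same sign in the authors' deposited table and 0 with the opposite sign.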

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

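The tests with limma-trend and with length and GC trends removed were chosen after the data were seen; the other alternatives were planned. The planned edgeR and DESeq2 alternatives were not run, because missing genes written as question marks kept the counts from being entered in that unit, and alternatives for normalized values did not apply. Single genes were compared only where the naming rule had picked them, by large changes, small p-values or the fixed set. Among these genes and the lists no called result reversed. Of 8233 comparisons of such genes 7275 kept direction and side of the threshold, 683 lost the call and 228 gained one. These numbers do not measure how stable calls are over all tested genes. Of 2094 comparisons of lists, the X- and Y-linked lists left out, the numbers were 1953, 66 and 30. With the letters as a replicate block 4032 genes changed with oxamate (4161 with trends also removed), 5376 with octyl-L-2HG against oxamate with trends also removed, and 441 were moved back (496); same-letter correlations in octyl-L-2HG against oxamate were 0.31, 0.39 and 0.04. At an adjusted p under 0.01 the counts of the 3 comparisons were 373, 2220 and 4562, with 3 genes moved back; at 2-fold or more they were 287, 2320 and 3041, with 8 moved back and 0.13 for raised genes in held-out libraries. These stricter limits lower counts by construction. With no filter on low counts 60 genes were moved back, 10 lists were called with octyl-L-2HG against oxamate, and medians were 0.09 for Y-linked genes with oxamate and -0.04 for X-linked genes with octyl-L-2HG against untreated. With at least 1 CPM in 3 libraries the Y-linked median was 0.18 (adjusted p = 0.13). With an estimated correlation 0 lists were called in each comparison, at unchanged medians of 0.25, -0.91 and -0.63 for X-linked and 0.23 and -0.84 for Y-linked genes. Leaving out 1 library gave 344 to 2295, 2298 to 3715 and 5309 to 7338 changed genes, 9 to 171 moved back, 0.14 to 0.29 for raised and -0.09 to 0.2 for lowered genes in held-out libraries, and 11 to 14, 5 to 11 and 9 to 13 lists. Medians then ran from 0.14 to 0.25 for Y-linked genes with oxamate and from -0.65 to -0.28 with octyl-L-2HG against untreated. Where no construction is named, the cause was not tested. Depth limits low genes: in simulated data 36.4% of 4-fold changes were recovered below a mean of 50 counts and 95.5% above it.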

Other observations

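Some members of other gene groups changed. Among NRF2 targets 3 of 18 tested genes fell and 1 rose with octyl-L-2HG against oxamate, also when adjusted over the list alone: Osgin1 had a log2 change of -3.09, the sulfiredoxin Srxn1 -2.31 and the superoxide dismutase Sod1 -0.81. Spermatid markers fell in the same libraries, 20 of 27 round and 17 of 20 elongating. In cholesterol synthesis 3 of 22 tested genes rose with oxamate (5 rose and 1 fell when adjusted over the list alone), with Hmgcs1 at 0.69, Insig1 at 1.12 and Nsdhl at 0.88. In the TCA cycle Fh1, fumarate hydratase, was the 1 gene of 23 that fell with octyl-L-2HG, at -1.70, again in the libraries in which spermatid markers fell. None of these 3 lists passed its test in that comparison.

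The tests of explanations below were chosen after the results were seen, and only the splits of libraries were planned before. Their 95% intervals come from 2000 resamplings of genes, not of libraries. They leave out the spread between libraries and treat genes as independent, so they are likely too narrow. For X-linked genes in oxamate against untreated the estimated inter-gene correlation was 0.25. The limit of the test on spermatid shares was tightened, to hold under 4 scalings, after its first values had been seen; this turned it from excluding that explanation to leaving it open.

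Spermatid markers and sex-linked genes were lower with octyl-L-2HG, with a median log2 change of -0.94 over the 4 lists. Scaling by library size alone left the median at -0.98, and removing trends with length and GC content left it at -0.92, so neither accounts for the whole pattern. A smaller share of 1 population of spermatids would lower its transcripts in 1 ratio between libraries. In 2 of 3 pairs of octyl-L-2HG libraries the ratio differed between deeper and shallower falls under all 4 scalings, and both include library C; in the pair of A and B it differed by -0.0657 (-0.0928 to -0.0177) under TMM and also under 2 other scalings, but the interval held 0 with library size alone (-0.0518 to 0.00649). These values count against 1 shared ratio, but since the pair without library C depends on the scaling, a smaller share of spermatids cannot be told apart from lower expression within cells.

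X-linked genes were higher with oxamate, with a median log2 change of 0.25 (95% interval 0.19 to 0.3). More spermatids would raise spermatid markers, whose median was -0.19 (-0.32 to -0.07), so these values argue against more spermatids. RNA of somatic testis cells would raise their markers, whose median over 34 tested genes was -0.12 (-0.28 to 0.05). Of these 2 rose and 3 fell. Most somatic markers were too low to test, so this median cannot decide on somatic RNA. A changed mix of germ cell stages before the spermatids was not tested. With trends with length and GC content removed the median was 0.19 (0.13 to 0.27), so these trends do not account for the whole of it. An effect of oxamate on X-linked expression within the spermatocytes stays open and was not tested. It cannot be told apart from an effect of time in culture, since no culture time was given for the untreated cells.

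Ribosomal protein and respiratory chain genes were lower with oxamate, with a median log2 change of -0.22 (-0.26 to -0.18). With trends with length and GC content removed it was -0.16 (-0.21 to -0.13), so these trends could account for part of the pattern and not the whole. Scaling by library size alone gave -0.21. No biological explanation was tested. Here too oxamate cannot be told apart from time in culture.

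In each comparison 1 of 10 splits of the 6 libraries, the real one, gave as many genes; 10 splits are too few for a share under 0.05. The real values were 1747, 3550 and 6988 genes, and the highest of the other splits gave 0, 1 and 0.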
